A study of Mus musculus with 26 samples.

How the data were processed

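Polyadenylated RNA of mouse CD4+ T cells was sequenced by the authors as 26 libraries, prepared with RNeasy Plus kits and the TruSeq stranded mRNA kit. Per the labels, reads were processed against the mouse genome build mm9. The software named is bcl2fastq 2.20.0.442, Trim Galore 0.4.2, TopHat2 2.1.1, SAMtools 1.7, Picard 2.5.0, R 3.6.1 and edgeR 3.26.6, and neither the counting tool nor the annotation release is stated. The deposited count tables hold whole numbers of reads over the exons of 21761 genes, 92 of them without a symbol, for 20 libraries in a first table and 6 in a second. The deposited FPKM tables equal the count divided by the library total and the exon length. A table of RPM values was not used here.

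Groups and comparisons were fixed before the data were examined, as were 30 gene lists, the tests, the alternatives and the rule for naming genes. Each library took its group from its label, the ex vivo Treg libraries from the group in their column names, which carry numbers that match no single sample. The lists were Treg core, effector Treg, naive and memory, IL-2 and STAT5 response, TGF-beta response, retinoic acid response, DNA methylation and hydroxymethylation machinery, Th1, Th2, Th17, Tfh, cytotoxic, homing receptors, T cell receptor early response, cell cycle, p53 response, glycolysis, hypoxia response, cholesterol synthesis, amino acid stress response, NRF2 antioxidant response, interferon response, interleukin and cytokine transcripts, and markers of invariant NKT, CD8 T, B, myeloid and dendritic, erythroid and platelet, NK and innate lymphoid cells and immature thymocytes. All lists with at least 5 tested genes were tested in every comparison. The report gives each of them for the Tet2/3-deficient cells, and for the other comparisons it describes lists chosen after their values were seen, beside the number that passed. The naming rule took genes followed everywhere, 24 of them counted in the report, the 8 largest changes in each direction with a mean of at least 10 CPM, and up to 4 called members of each list with the largest change. Which of these to describe was chosen after their values were seen, and some genes under these rules are not reported here.

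Counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM factors, the filterByExpr filter and robust quasi-likelihood tests, 2-sided, with Benjamini-Hochberg adjustment over the genes of each comparison and a threshold of 0.05. The 6 cultured and naive groups of the first table shared a fit of 12 libraries. The other comparisons were fitted on their own libraries. Residual degrees of freedom were 6 in the shared fit and for the Tet2/3-deficient cells, and 4 for control Treg against naive cells and for restimulation. The SE of a log2 fold change is its size over the square root of the F statistic. Levels beside a gene are CPM over TMM-scaled library totals, while values per library and summed markers are CPM over raw totals. Against a group with 0 counts a fold is a lower bound computed from 3 counts over the group, and with 1 to 3 counts it is a ratio of CPM with an exact 95% counting interval. These bounds and intervals cover counting error alone. Lists and gene sets were tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and with an estimated one, and with fry, all adjusted by Benjamini-Hochberg.

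Alternatives were DESeq2 1.42.0, RLE factors, no count filter, a required log2 fold change of 1, limma 3.58.1 with a trend on log2 FPKM plus 1, a replicate block, other sets of libraries in the fit, and leaving out each library in turn. Those chosen after seeing the data are so named. In simulated counts, edgeR recovered 50.7%, 85.1% and 97% of planted 1.5-fold, 2-fold and 4-fold changes at the size of the Tet2/3-deficient comparison. False calls were 7.74% there. Recovery was 61.2%, 88.1% and 98.5% at the size of the vitamin C comparison. In 100 random lists camera called 0 under 0.05 and fry 7, but random genes cannot test correlated lists. Replicate libraries were no copies (chi-square per degree of freedom 2.289 to 23.6).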

Results

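Messenger RNA was sequenced from 26 libraries of mouse CD4+ T cells, taken from spleen and lymph nodes of C57BL/6 mice and sorted or cultured. In a first table, 12 libraries came from Foxp3-eGFP reporter mice of 5 to 6 weeks, whose eGFP marks cells expressing Foxp3, the transcription factor that defines regulatory T (Treg) cells. These were naive CD4+ cells, cells activated through CD3 and CD28 without TGFb (Th0), and induced Treg (iTreg) cultures with TGFb alone, with vitamin C, with retinoic acid, or with both (n = 2 libraries per group). The same table held Treg cells sorted ex vivo at 3 weeks from mice with floxed Tet2 and Tet3 and the CD4-Cre transgene (Tet2/3-deficient, n = 4) and from mice of the same floxed genotype without Cre (control, n = 4). TET enzymes oxidise 5-methylcytosine and use vitamin C as a cofactor. A separate table held Foxp3-positive iTreg sorted at day 6 (n = 3) and cells that had become Foxp3-negative after restimulation (n = 3), from mice of 12 to 14 weeks. Total counts per library were 9647669 to 11640223 in the naive and cultured cells of the first table, 13397602 to 17672302 in the ex vivo Treg cells and 11293704 to 17219805 in the restimulation table. Values below are log2 fold changes ± SE from edgeR unless stated, and levels are CPM, mean ± SD. The labels do not say that replicates are separate animals or cultures, so each p measures the spread between samples.

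The comparison of Tet2/3-deficient with control Treg cells asks what deletion of both genes, which rests on the labels, changed. Tet2 transcripts were counted at 16.5, 12.7, 15.9 and 12 CPM in the 4 Tet2/3-deficient libraries and at 15, 14.2, 9.96 and 15.7 CPM in the 4 control libraries, a difference that did not pass the test (0.02 ± 0.15, edgeR quasi-likelihood test, adjusted p = 0.93). Tet3 was counted at 113, 96.3, 98.4 and 114 CPM in the Tet2/3-deficient and 161, 132, 126 and 172 CPM in the control libraries, and fell 1.44-fold (-0.52 ± 0.10, edgeR, adjusted p = 0.00255). The counts sum all exons of a gene, and reads over the floxed exons alone were not analysed here.

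**Figure D1:**
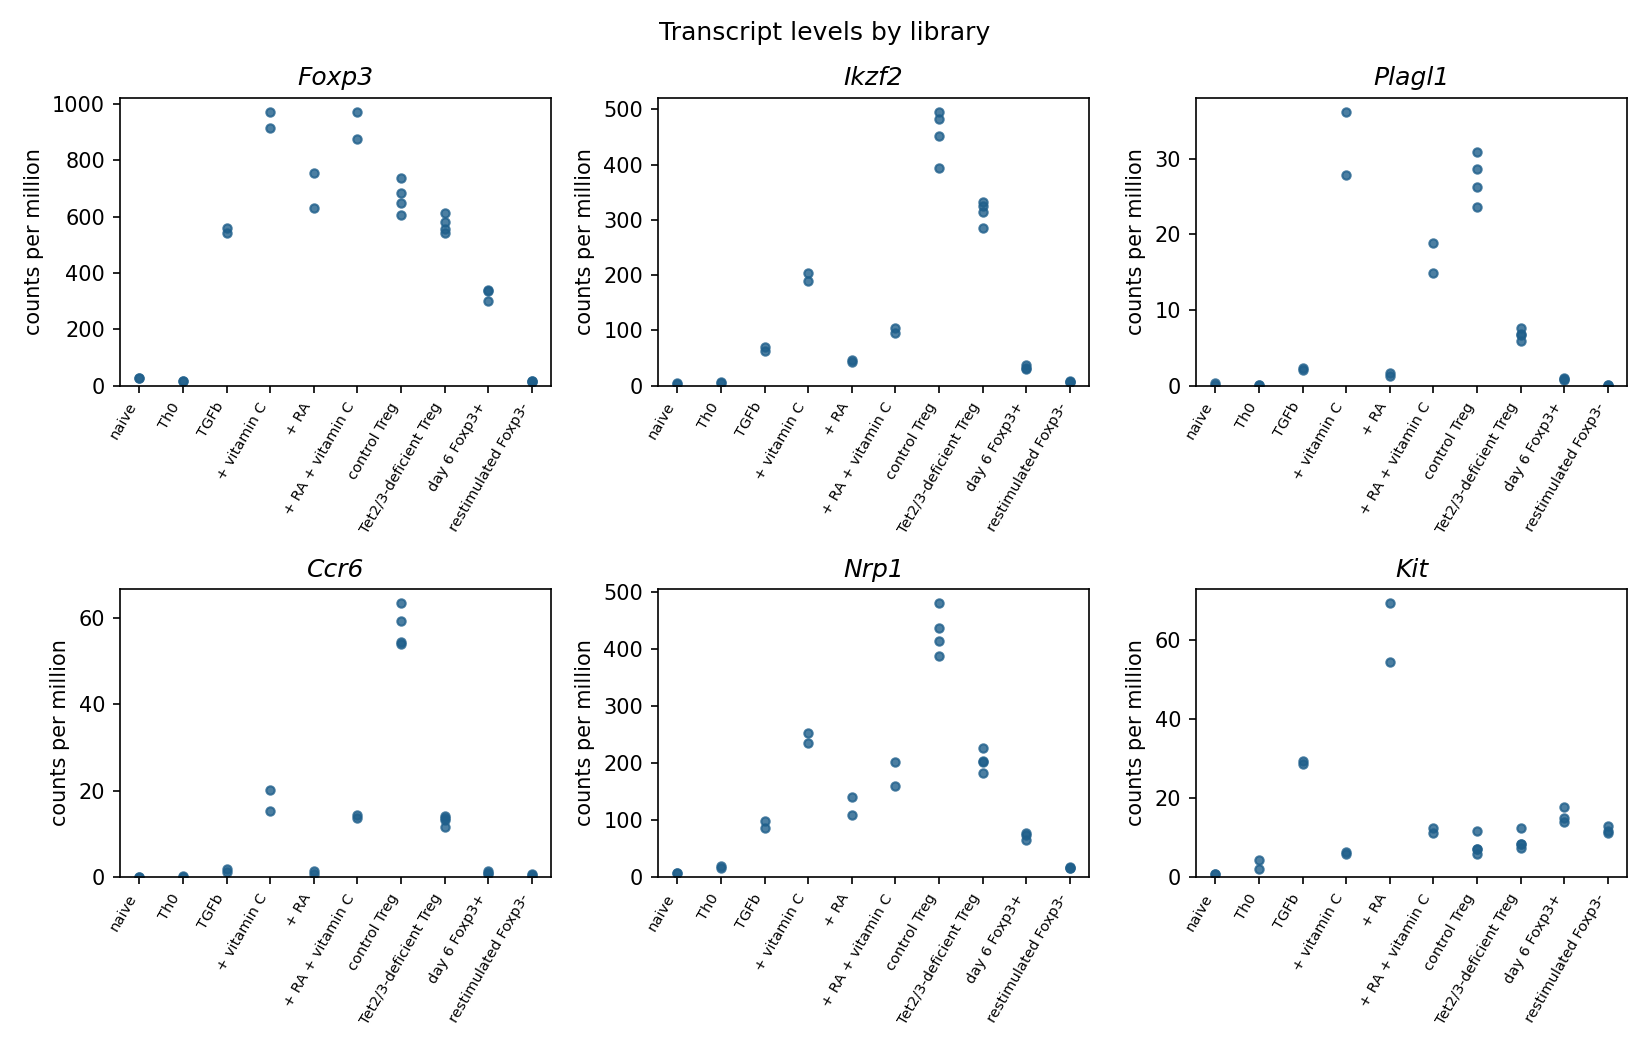
Transcript levels of 6 genes in CPM of each library total, on linear axes from 0, with 1 point per library in each of the 10 groups. Ikzf2, Plagl1, Ccr6 and Nrp1 were lower in each Tet2/3-deficient than in each control Treg library, while the Foxp3 libraries overlapped on this scale. These 5 genes were higher in both vitamin C libraries than in both TGFb libraries.

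Tet2/3-deficient Treg cells expressed less of several Treg genes than control cells (n = 4 and 4 libraries). Il10, which encodes an anti-inflammatory cytokine, fell 20.4-fold to 0.257 ± 0.15 against 5.36 ± 0.42 CPM (-4.35 ± 0.29, edgeR, adjusted p = 1.74e-06). The inhibitory receptor gene Klrg1 fell 4.18-fold (-2.06 ± 0.28), the zinc finger gene Plagl1 fell 4.13-fold (-2.05 ± 0.12), and Nrp1, the semaphorin and VEGF co-receptor that marks thymic Treg cells, fell 2.17-fold (-1.12 ± 0.08). Foxp3 itself fell 1.2-fold, from 677 to 565 CPM (-0.26 ± 0.07, edgeR, adjusted p = 0.0113), and the Ikaros family genes Ikzf2 (-0.57 ± 0.08) and Ikzf4 (-0.86 ± 0.08) fell with it. Penk, the precursor of enkephalins, rose 5.68-fold (2.51 ± 0.16), and Itgae, the CD103 integrin chain, rose 1.91-fold (0.93 ± 0.11). In the Treg core list, 17 of 34 fell, 6 rose and 11 did not pass (19 and 6 adjusted over the list alone, camera adjusted p = 6.16e-06, or adjusted p = 0.118 with an estimated correlation). In the effector Treg list, 7 of 20 fell, 5 rose and 8 did not pass (9 and 6 adjusted over the list alone, camera adjusted p = 0.0752). Its falls included Il1rl1 (-2.75 ± 0.26), the receptor for IL-33, and Rora (-1.61 ± 0.16), a nuclear receptor.

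Genes of killer lymphocytes rose in the Tet2/3-deficient cells. Gzma, which encodes granzyme A, rose 12.9-fold to 12.9 ± 6.5 against 1 ± 0.59 CPM (3.69 ± 0.51, edgeR, adjusted p = 0.00114). The chemokine genes Ccl4 (3.35 ± 0.35), Ccl3 (3.06 ± 0.61) and Xcl1 (2.13 ± 0.23) rose, and so did Prf1 (1.59 ± 0.13), which encodes perforin. Eomes, a T-box factor of cytotoxic and memory cells, rose 7.11-fold (2.83 ± 0.17), and the cytotoxic granule gene Nkg7 rose 3.57-fold (1.84 ± 0.09). Across the cytotoxic list, 13 of 19 rose and 6 did not pass (13 and 2 adjusted over the list alone, camera adjusted p = 4.8e-08, or adjusted p = 0.133 with an estimated correlation). Among invariant NKT markers 5 of 10 rose, 2 fell and 3 did not pass (5 and 2 adjusted over the list alone, camera adjusted p = 0.00189, or adjusted p = 0.277 with an estimated correlation). Their summed level was 1780 ± 72 CPM against 1590 ± 110 CPM in control cells. For the CD8 T cell markers, 5 of 7 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.0393, or adjusted p = 0.205 with an estimated correlation). Their summed level was 176 ± 19 against 93.4 ± 3.6 CPM. The CD8 chains themselves were the members that fell, Cd8b1 7.85-fold (-2.97 ± 0.13) and Cd8a 4.42-fold (-2.14 ± 0.30). Of the NK and innate lymphoid markers 4 of 10 rose, 1 fell and 5 did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.216), and they summed to 491 ± 83 against 524 ± 130 CPM. The gene of the NK1.1 receptor, Klrb1c (1.26 ± 0.18), rose.

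Lineage genes of helper T cells moved both ways. In the Th1 list 8 of 19 fell, 6 rose and 5 did not pass (10 and 7 adjusted over the list alone, camera adjusted p = 0.981). Its rises included Il12rb2 (2.12 ± 0.27), an IL-12 receptor chain, while Hopx (-1.99 ± 0.09) and Ifng (-1.46 ± 0.31) fell. In the Th17 list 5 of 11 fell, 1 rose and 5 did not pass (5 and 1 adjusted over the list alone, camera adjusted p = 0.00189, or adjusted p = 0.133 with an estimated correlation). The homing receptor gene Ccr6 fell 4.5-fold (-2.17 ± 0.09) while the IL-23 receptor gene Il23r rose 3.12-fold from a low level (1.33 ± 0.095 against 0.428 ± 0.14 CPM). Of the Tfh list, 4 of 13 fell, 1 rose and 8 did not pass (5 and 1 adjusted over the list alone, camera adjusted p = 0.00951, or adjusted p = 0.133 with an estimated correlation). Among the falls were Angptl2 (-4.01 ± 0.22) and Pdcd1 (-0.72 ± 0.11), which encodes PD-1. Of the Th2 list, 4 of 11 fell, 2 rose and 5 did not pass (6 and 2 adjusted over the list alone, camera adjusted p = 0.168). Among homing receptors, 10 of 25 fell, 2 rose and 13 did not pass (15 and 4 adjusted over the list alone, camera adjusted p = 0.000158, or adjusted p = 0.277 with an estimated correlation). The falls included Ccr10 (-1.94 ± 0.32), Cxcr6 (-1.10 ± 0.18) and Itgb1 (-1.02 ± 0.07). In the list of interleukin and cytokine transcripts, 7 of 20 fell, 5 rose and 8 did not pass (8 and 5 adjusted over the list alone, camera adjusted p = 0.213).

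Cell cycle genes rose in the Tet2/3-deficient cells. Cdc45, part of the replicative helicase, rose 2.71-fold (1.44 ± 0.35, edgeR, adjusted p = 0.0184). In the cell cycle list, 18 of 40 rose and 22 did not pass (36 adjusted over the list alone, camera adjusted p = 1.59e-09, or adjusted p = 0.559 with an estimated correlation). Its median log2 fold change was 1.21. Hypoxia response genes were higher as a list too. There 12 of 24 rose, 4 fell and 8 did not pass (12 and 4 adjusted over the list alone, camera adjusted p = 0.0402, or adjusted p = 0.205 with an estimated correlation). These included Ak4 (2.03 ± 0.38), a mitochondrial adenylate kinase, and Nrn1 (1.31 ± 0.13), which encodes neuritin. Of the glycolysis genes 6 of 23 rose, 4 fell and 13 did not pass (6 and 4 adjusted over the list alone, camera adjusted p = 0.616). Hexokinase 2, Hk2 (0.85 ± 0.15), rose and Aldoc (-0.90 ± 0.15) fell. In the amino acid stress list 9 of 20 rose, 3 fell and 8 did not pass (9 and 3 adjusted over the list alone, camera adjusted p = 0.147). Asparagine synthetase, Asns (1.19 ± 0.22), rose and Trib3 (-1.74 ± 0.29) fell. In the cholesterol synthesis list, 5 of 28 fell, 4 rose and 19 did not pass (5 and 4 adjusted over the list alone, camera adjusted p = 0.394).

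Signalling and stress genes moved both ways. In the retinoic acid list 7 of 16 fell, 2 rose and 7 did not pass (9 and 2 adjusted over the list alone, camera adjusted p = 0.0133, or adjusted p = 0.343 with an estimated correlation). The falls included Dhrs3 (-1.27 ± 0.22), a retinal reductase, and the receptor gene Rarg (-0.84 ± 0.06). In the TGF-beta list 10 of 23 fell, 3 rose and 10 did not pass (11 and 4 adjusted over the list alone, camera adjusted p = 0.136). Serpine2 (2.92 ± 0.18) rose and Ctgf (-3.04 ± 0.51) fell. Of IL-2 and STAT5 response genes 7 of 24 fell, 5 rose and 12 did not pass (10 and 5 adjusted over the list alone, camera adjusted p = 0.303). A suppressor of cytokine signalling, Cish (-0.89 ± 0.08), fell. Of naive and memory genes 10 of 24 fell, 4 rose and 10 did not pass (10 and 5 adjusted over the list alone, camera adjusted p = 0.145). The gene for the lymph node exit receptor, S1pr1 (-0.75 ± 0.09), fell and Pdlim4 (2.81 ± 0.24) rose. In the list of DNA methylation and hydroxymethylation machinery, 7 of 22 rose, 4 fell and 11 did not pass (7 and 4 adjusted over the list alone, camera adjusted p = 0.267). Cxxc5 (0.88 ± 0.16) and Mbd4 (0.57 ± 0.11) rose. Of early T cell receptor response genes 5 of 25 fell, 4 rose and 16 did not pass (6 and 4 adjusted over the list alone, camera adjusted p = 0.948), with Nr4a2 (1.60 ± 0.13) up. Of the p53 list 6 of 20 fell, 2 rose and 12 did not pass (6 and 2 adjusted over the list alone, camera adjusted p = 0.948), with Sesn2 (0.85 ± 0.13) up. Of NRF2 antioxidant genes 7 of 26 rose, 4 fell and 15 did not pass (7 and 6 adjusted over the list alone, camera adjusted p = 0.62). The glutathione transferase gene Gsta4 fell 11.9-fold (-3.57 ± 0.34). In the interferon list 3 of 46 fell, 1 rose and 42 did not pass (2 and 0 adjusted over the list alone, camera adjusted p = 0.384), with Irf1 (-0.51 ± 0.12) and Ly6e (-0.61 ± 0.07) lower. Median and camera direction differed in sign for the p53 and immature thymocyte lists (medians 0.05 and 0.01, lower by camera), and median and mean for the early T cell receptor (-0.04 and 0.05), NRF2 (0.07 and -0.05) and immature thymocyte lists (0.01 and -0.51).

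Markers of other cell types were present in the sorted Treg libraries. Among myeloid and dendritic markers 4 of 21 rose and 17 did not pass (2 adjusted over the list alone, camera adjusted p = 0.0752). Itgam (2.14 ± 0.29), the CD11b chain, and Ctsh (1.39 ± 0.22) rose, with summed levels of 265 ± 54 in Tet2/3-deficient against 188 ± 22 CPM in control cells. For B cell markers, 0 of 18 passed in edgeR (0 adjusted over the list alone, camera adjusted p = 0.368), with summed levels of 248 ± 39 against 277 ± 110 CPM. Of erythroid and platelet markers 1 of 7 rose, 1 fell and 5 did not pass (1 and 1 adjusted over the list alone, camera adjusted p = 0.192). The red cell anion exchanger gene Slc4a1 (-1.24 ± 0.25) fell, with sums of 405 ± 130 against 669 ± 240 CPM. Of immature thymocyte markers 2 of 8 fell, 1 rose and 5 did not pass (3 and 1 adjusted over the list alone, camera adjusted p = 0.0521), with sums of 184 ± 9.9 against 190 ± 19 CPM.

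Large single changes also lay outside these lists. Higher were Homer2 (4.47 ± 0.26), a synaptic scaffold gene, Fn1, which encodes fibronectin, 13.6-fold (3.77 ± 0.16), and Ceacam1 (2.71 ± 0.38). Lower were Ptpn5, a tyrosine phosphatase gene, 63.5-fold to 0.248 ± 0.12 CPM (-5.99 ± 0.22), and Prg4, which encodes lubricin, 33.8-fold (-5.08 ± 0.18). Gabrr2 (-5.00 ± 0.29) and Sh3gl3 (-4.71 ± 0.18) were lower too. Of 24 genes followed in every comparison, 4 were higher, 8 lower and 8 did not pass, and Il4, Il13, Il17a and Il2 were under the count filter. Besides those above, the maintenance and de novo DNA methyltransferase genes Dnmt1 (0.47 ± 0.08), Dnmt3a (0.29 ± 0.07) and Dnmt3b (0.40 ± 0.12) rose and Tbx21, the Th1 factor, fell (-0.78 ± 0.27, edgeR, adjusted p = 0.0476). The call of Dnmt3b was lost without Tet2/3-deficient S6 (0.0557), without Tet2/3-deficient S7 (0.0794), without control S2 (0.06) and without control S4 (0.0595) (edgeR adjusted p in parentheses). That of Tbx21 was lost with no count filter (0.0566), without Tet2/3-deficient S5 (0.0954), without Tet2/3-deficient S8 (0.105), without control S2 (0.0784), without control S3 (0.106), without control S4 (0.0991) and without control S1 and S3 (0.0965). Besides Tet2, not passing were Ctla4 (0.03 ± 0.11), Tnfrsf18 (-0.11 ± 0.06), Gata3 (-0.02 ± 0.08), Bcl6 (-0.29 ± 0.24), Tet1 (0.34 ± 0.19), Il2ra (-0.17 ± 0.08) and Ccr9 (-0.47 ± 0.17). Of these Tet1 passed without control S1 (0.0218), Il2ra passed without Tet2/3-deficient S5 (0.0089), and Ccr9 passed in DESeq2 (0.0329), with all 20 libraries fitted (0.0176), without Tet2/3-deficient S6 (0.0468), without control S1 (0.00144) and without control S1 and S3 (0.00261).

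By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 3800 of 11679 tested genes changed, 1953 higher and 1847 lower, and 642 of them by a log2 fold change of 1 or more. With limma on the FPKM values, 2419 were higher and 1462 lower (62.3% against 51.4% higher in edgeR). The calls of the 10 lists that passed camera were all lost with an estimated correlation. Fry passed 18, testing whether genes of a list move one way and not whether they differ from other genes.

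Adding vitamin C to TGFb asks how the cofactor changed iTreg cells (n = 2 and 2 libraries). Foxp3 rose 1.69-fold, from 549 ± 13 to 926 ± 47 CPM (0.76 ± 0.09, edgeR quasi-likelihood test, adjusted p = 9.73e-05). Other Treg genes rose further, the Helios gene Ikzf2 2.91-fold (1.54 ± 0.13), Nrp1 2.62-fold (1.39 ± 0.14) and Plagl1 14.3-fold (3.84 ± 0.22). In the Treg core list 15 of 30 rose and 15 did not pass (18 adjusted over the list alone, camera adjusted p = 4.47e-17, or adjusted p = 0.208 with an estimated correlation). Its rises included Cd83 (1.76 ± 0.24), an activation marker, and Gbp3 (1.45 ± 0.15), an interferon-induced GTPase. In the effector Treg list 3 of 16 rose and 13 did not pass (5 adjusted over the list alone, camera adjusted p = 0.0083, or adjusted p = 0.428 with an estimated correlation). The transcription factor genes Maf (2.51 ± 0.34) and Myb (1.06 ± 0.17) and the chemokine receptor gene Ccr4 (0.87 ± 0.14) rose.

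Some homing receptor genes rose too. Ccr6, the CCL20 receptor, rose 12.3-fold (17.4 ± 3.4 against 1.4 ± 0.57 CPM, 3.63 ± 0.30), and Gpr15, a receptor for colon homing, rose 7.12-fold (18.6 ± 5.4 against 2.58 ± 1.6 CPM, 2.83 ± 0.36). In the homing list 6 of 23 rose, 2 fell and 15 did not pass (7 and 3 adjusted over the list alone, camera adjusted p = 0.0123, or adjusted p = 0.428 with an estimated correlation). In the Tfh list 5 of 12 rose, 1 fell and 6 did not pass (6 and 1 adjusted over the list alone, camera adjusted p = 0.0342, or adjusted p = 0.299 with an estimated correlation), with the PD-1 gene Pdcd1 (1.39 ± 0.20) up. In the TGF-beta list 6 of 22 rose, 1 fell and 15 did not pass (6 and 1 adjusted over the list alone, camera adjusted p = 0.0123, or adjusted p = 0.336 with an estimated correlation). Skil (0.93 ± 0.11), a feedback repressor of SMAD signalling, and Bhlhe40 (1.08 ± 0.16) rose, while Serpine2 (-2.19 ± 0.42) fell. In the interferon list 6 of 45 rose and 39 did not pass (6 adjusted over the list alone, camera adjusted p = 0.00183, or adjusted p = 0.528 with an estimated correlation), with Gbp2 (1.12 ± 0.16) up. Of immature thymocyte markers 4 of 8 rose and 4 did not pass (4 adjusted over the list alone, camera adjusted p = 0.00766, or adjusted p = 0.336 with an estimated correlation). Among them were Dntt (1.44 ± 0.24), which encodes terminal transferase, Cd24a (1.25 ± 0.24) and Cd8b1 (0.76 ± 0.13), and the summed level was 260 ± 2.8 against 246 ± 2.8 CPM.

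Growth and metabolic genes fell with vitamin C. In the cell cycle list 26 of 40 fell and 14 did not pass (35 adjusted over the list alone, camera adjusted p = 6.8e-15, or adjusted p = 0.232 with an estimated correlation). Examples were Cdca8 (-0.62 ± 0.11), a chromosome passenger gene, and Mcm3 (-0.53 ± 0.09), part of the replicative helicase. In the glycolysis list 13 of 23 fell and 10 did not pass (13 adjusted over the list alone, camera adjusted p = 1.65e-05, or adjusted p = 0.393 with an estimated correlation). In the cholesterol list 18 of 29 fell, 2 rose and 9 did not pass (20 and 2 adjusted over the list alone, camera adjusted p = 1.01e-08, or adjusted p = 0.393 with an estimated correlation), with farnesyl diphosphate synthase, Fdps (-0.86 ± 0.15), and Acat2 (-0.80 ± 0.14) down. In the amino acid stress list 6 of 21 fell, 1 rose and 14 did not pass (8 and 2 adjusted over the list alone, camera adjusted p = 0.00886, or adjusted p = 0.428 with an estimated correlation). The amino acid transporter gene Slc7a5 (-0.73 ± 0.12) and the serine pathway gene Shmt2 (-0.61 ± 0.10) fell there. Uhrf1, the partner of DNMT1, fell too (-0.49 ± 0.08).

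Large single rises were those of Popdc2, 358 counts against 2 (179-fold, exact 95% counting interval 49.3 to 1490), Frmd5, 21.1-fold (4.40 ± 0.23), Cited4 (3.02 ± 0.27) and Muc1 (2.65 ± 0.17), which encodes mucin 1. Mctp1 fell 12.6-fold (-3.66 ± 0.19), Kit, the stem cell factor receptor, 4.9-fold (-2.29 ± 0.20), and Vipr1 (-1.82 ± 0.15) fell too. Of the 24 followed genes 7 rose and 10 did not pass. Tbx21, Ifng, Il4, Il13, Il17a, Il2 and Il10 were under the count filter in this and the other comparisons of cultured cells in the first table. Also rising were Tet1 (0.81 ± 0.25), Il2ra (0.33 ± 0.08), Ikzf4 (0.84 ± 0.18) and Bcl6 (0.79 ± 0.18). The call of Tet1 was lost in DESeq2 (0.0603), in limma on FPKM values (0.177), with only the compared groups fitted (0.0909), without TGFb 2 (0.297) and without vitamin C 1 (0.319), where values in parentheses are adjusted p, by edgeR unless another tool is named. That of Il2ra was lost without TGFb 1 (0.117), without vitamin C 1 (0.0702) and without vitamin C 2 (0.0766), that of Ikzf4 without TGFb 1 (0.0812) and without vitamin C 2 (0.0612), and that of Bcl6 without TGFb 1 (0.0585) and without vitamin C 2 (0.06). Not passing were Tet2 (0.48 ± 0.16), Tet3 (0.30 ± 0.15), Dnmt1 (-0.34 ± 0.11), Dnmt3a (-0.02 ± 0.10), Dnmt3b (-0.05 ± 0.15), Ctla4 (0.38 ± 0.15), Tnfrsf18 (0.15 ± 0.15), Itgae (0.05 ± 0.42), Gata3 (0.11 ± 0.09) and Ccr9 (0.63 ± 0.72). Of these Tet2 passed with no count filter (0.0303) and without vitamin C 2 (0.0378), Dnmt1 in DESeq2 (0.0403), with no count filter (0.0296) and with only the compared groups fitted (0.0205) and Ctla4 with only the compared groups fitted (0.0167).

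In edgeR 1900 of 11287 genes changed, 998 higher and 902 lower. The count was 1001 without vitamin C 1, 908 without vitamin C 2, 771 without TGFb 1 and 830 without TGFb 2, the lone library being assumed to vary like the other groups. Of 29 lists 14 passed camera, 0 with an estimated correlation, and 14 passed fry.

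Retinoic acid, a vitamin A metabolite that imprints gut homing, was added to TGFb in another culture (n = 2 and 2 libraries). Cyp26b1, which degrades retinoic acid, was at 52.3 ± 10 CPM against 0 in both TGFb libraries, at least 379-fold higher. The gut homing receptor gene Ccr9 rose from 0.233 ± 0.073 to 383 ± 23 CPM (10.61 ± 0.22, edgeR quasi-likelihood test, adjusted p = 1.15e-13), Dhrs3 rose 11.8-fold (3.57 ± 0.35) and Itgae 3.77-fold (1.91 ± 0.35). In the retinoic acid list 6 of 15 rose, 4 fell and 5 did not pass (6 and 5 adjusted over the list alone, camera adjusted p = 1.86e-09, or adjusted p = 0.11 with an estimated correlation), with a median of -0.03 and a mean of 1.76. Of immature thymocyte markers 4 of 8 rose, 1 fell and 3 did not pass (5 and 1 adjusted over the list alone, camera adjusted p = 7.64e-23, or adjusted p = 0.0129 with an estimated correlation). They include Ccr9, Dntt (3.17 ± 0.20) and Cd24a (2.02 ± 0.23). Their summed level was 723 ± 33 against 246 ± 2.8 CPM, with most of the rise from Ccr9. In the naive and memory list 11 of 24 rose, 5 fell and 8 did not pass (13 and 5 adjusted over the list alone, camera adjusted p = 0.000558, or adjusted p = 0.244 with an estimated correlation), with Actn1 (1.57 ± 0.14) up and Dapl1 (-2.23 ± 0.26) down. In the Treg core list 12 of 30 fell, 6 rose and 12 did not pass (13 and 9 adjusted over the list alone, camera adjusted p = 0.00873, or adjusted p = 0.379 with an estimated correlation), with Ecm1 (-2.15 ± 0.11) down and, in the effector Treg list, Ccr8 (-1.66 ± 0.25).

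Lipid, sugar and division genes fell. In the cholesterol list 25 of 29 fell and 4 did not pass (25 and 1 adjusted over the list alone, camera adjusted p = 4.32e-28, or adjusted p = 0.11 with an estimated correlation). Stearoyl-CoA desaturase, Scd1 (-3.29 ± 0.36), and HMG-CoA synthase, Hmgcs1 (-1.27 ± 0.14), fell. In the cell cycle list 38 of 40 fell and 2 did not pass (40 adjusted over the list alone, camera adjusted p = 9.86e-20, or adjusted p = 0.11 with an estimated correlation), with Aurkb (-0.71 ± 0.12) and Ndc80 (-0.65 ± 0.10). In the glycolysis list 15 of 23 fell and 8 did not pass (16 adjusted over the list alone, camera adjusted p = 3.25e-10, or adjusted p = 0.244 with an estimated correlation), with the lactate exporter gene Slc16a3 (-2.35 ± 0.32) and Tpi1 (-1.10 ± 0.17) down. In the hypoxia list 9 of 25 fell, 1 rose and 15 did not pass (17 and 1 adjusted over the list alone, camera adjusted p = 1.05e-05, or adjusted p = 0.371 with an estimated correlation), with Nrn1 (-2.48 ± 0.35). Large rises were those of Slc43a1 (4.46 ± 0.41), Plac8 (4.31 ± 0.59) and the follicle homing receptor gene Cxcr5 (3.03 ± 0.25). Falls were those of Ifitm1 (-4.80 ± 0.21), Lmna, which encodes lamin A (-4.25 ± 0.36), the p53 target Cdkn1a (-1.78 ± 0.16) and the beta-globin genes Hbb-bs (-5.24 ± 0.31) and Hbb-b1 (-4.46 ± 0.42).

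Of the followed genes 5 rose, 2 fell and 10 did not pass. Foxp3 rose 1.25-fold (0.32 ± 0.09), a call lost with only the compared groups fitted (0.0985), without retinoic acid 1 (0.282), without TGFb 1 (0.168) and without TGFb 2 (0.0924) (adjusted p, by edgeR unless named). The rise of Nrp1 (0.44 ± 0.14) was lost with RLE factors (0.0544), in limma on FPKM values (0.0716), with only the compared groups fitted (0.0673), without retinoic acid 1 (0.368), without TGFb 1 (0.267) and without TGFb 2 (0.0629). That of Bcl6 (0.66 ± 0.18) was lost in DESeq2 (0.119), with only the compared groups fitted (0.0659), without retinoic acid 2 (0.128), without TGFb 1 (0.129) and without TGFb 2 (0.0878). The fall of Dnmt1 (-0.38 ± 0.11) was lost in limma on FPKM values (0.0554), with only the compared groups fitted (0.0812), without retinoic acid 2 (0.176), without TGFb 1 (0.189) and without TGFb 2 (0.0527), and that of Ikzf2 (-0.58 ± 0.14) without TGFb 2 (0.0628). Not passing were Tet1 (0.27 ± 0.27), Tet2 (0.15 ± 0.17), Tet3 (0.44 ± 0.15), Dnmt3a (-0.28 ± 0.10), Dnmt3b (0.31 ± 0.15), Il2ra (0.11 ± 0.08), Ctla4 (0.35 ± 0.15), Ikzf4 (0.19 ± 0.19), Tnfrsf18 (-0.41 ± 0.15) and Gata3 (0.06 ± 0.09). Of these Tet3 passed in DESeq2 (0.0463) and without retinoic acid 2 (0.00624), Dnmt3a with RLE factors (0.0498) and without TGFb 2 (0.0175) and Tnfrsf18 in DESeq2 (0.0249) and without retinoic acid 2 (0.0109). In edgeR 1860 of 11287 genes changed, 811 higher and 1049 lower. The count was 795 without TGFb 1 and 1060 without retinoic acid 1. Of 29 lists 15 passed camera, 1 with an estimated correlation, and 16 passed fry.

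Adding vitamin C to cultures with TGFb and retinoic acid (n = 2 and 2 libraries) also raised Treg genes. Ikzf2 rose 2.19-fold (1.13 ± 0.14, edgeR quasi-likelihood test, adjusted p = 8.53e-05), Ebi3, a subunit of IL-35 and IL-27, 2.21-fold (1.15 ± 0.12), and Plagl1 11.7-fold (3.55 ± 0.25). In the Treg core list 9 of 30 rose and 21 did not pass (12 adjusted over the list alone, camera adjusted p = 9.36e-09, or adjusted p = 0.134 with an estimated correlation), with Ccr8 (1.68 ± 0.25). Ccr6 rose 14-fold (3.81 ± 0.33), and the imprinted neighbours Igf2 and H19 rose 13.9-fold (3.79 ± 0.37) and 9.79-fold (3.29 ± 0.16). Of immature thymocyte markers 5 of 8 rose and 3 did not pass (5 adjusted over the list alone, camera adjusted p = 2.12e-12, or adjusted p = 0.0708 with an estimated correlation). They include Cd8a (2.62 ± 0.27), Cd24a (1.66 ± 0.20) and Ccr9 (0.81 ± 0.10), and summed to 1210 ± 28 against 723 ± 33 CPM. Of NK and innate lymphoid markers 4 of 7 fell, 1 rose and 2 did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.000865, or adjusted p = 0.134 with an estimated correlation), summing to 186 ± 2.1 against 303 ± 17 CPM. Markers of CD8 T, B and myeloid cells were higher by camera (adjusted p = 0.000217, 0.01 and 0.0221), but not with an estimated correlation (0.134, 0.155 and 0.134). In the naive and memory list 8 of 24 fell, 1 rose and 15 did not pass (13 and 3 adjusted over the list alone, camera adjusted p = 3.22e-05, or adjusted p = 0.138 with an estimated correlation), with S1pr1 (-0.85 ± 0.08) and Igfbp4 (-0.89 ± 0.10) down. In the cell cycle list 10 of 40 fell and 30 did not pass (33 adjusted over the list alone, camera adjusted p = 2.12e-12, or adjusted p = 0.134 with an estimated correlation), and Pgam1 (-0.52 ± 0.10), a glycolytic mutase, fell. Also higher were Cxcr5 (1.57 ± 0.18) and Adgre1 (3.05 ± 0.28), the F4/80 receptor. Also lower were Kit, 5.34-fold (-2.42 ± 0.17), Rnf144a (-2.78 ± 0.31) and Tnfsf8 (-1.46 ± 0.12), the CD30 ligand.

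Of the followed genes 6 rose, 1 fell and 10 did not pass. Foxp3 rose 1.32-fold (0.40 ± 0.09), a call lost with only the compared groups fitted (0.11), without retinoic acid 2 (0.111) and without retinoic acid plus vitamin C 1 (0.136) (adjusted p, by edgeR unless named). The rise of Tet1 (0.84 ± 0.24) was lost in DESeq2 (0.0662), in limma on FPKM values (0.184), with only the compared groups fitted (0.0625), without retinoic acid 1 (0.0669), without retinoic acid 2 (0.222), without retinoic acid plus vitamin C 1 (0.146) and without retinoic acid plus vitamin C 2 (0.123). That of Nrp1 (0.52 ± 0.13) was lost with only the compared groups fitted (0.122), without retinoic acid 2 (0.199) and without retinoic acid plus vitamin C 1 (0.235), and that of Itgae (1.02 ± 0.27) in DESeq2 (0.114), without retinoic acid 2 (0.225) and without retinoic acid plus vitamin C 1 (0.179). The fall of Gata3 (-0.37 ± 0.09) was lost with only the compared groups fitted (0.089), without retinoic acid 1 (0.0663), without retinoic acid 2 (0.0642), without retinoic acid plus vitamin C 1 (0.129) and without retinoic acid plus vitamin C 2 (0.102). Not passing were Tet2 (0.08 ± 0.16), Tet3 (0.09 ± 0.15), Dnmt1 (-0.21 ± 0.11), Dnmt3a (-0.02 ± 0.10), Dnmt3b (0.23 ± 0.14), Il2ra (0.26 ± 0.08), Ctla4 (0.33 ± 0.15), Ikzf4 (0.53 ± 0.18), Tnfrsf18 (-0.17 ± 0.15) and Bcl6 (0.14 ± 0.16). Of these Il2ra passed with no count filter (0.0473) and without retinoic acid 1 (0.0453). In edgeR 851 of 11287 genes changed, 487 higher and 364 lower. The count was 424 without retinoic acid 2, 460 and 438 without retinoic acid plus vitamin C 1 and 2, and 487 with only the compared groups fitted. Of 29 lists 12 passed camera, 0 with an estimated correlation, and 10 passed fry.

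Of the 1900 genes called with vitamin C alone 1818 (95.7%) had the same sign with retinoic acid, and 592 were called there in that direction. Higher in both settings were 361 genes, where independent calls would share 43.1, and lower in both 231, against 29.1 (Fisher's exact tests, p = 9.9e-295 and p = 1.9e-168, which treat genes as independent). The difference of the 2 vitamin C effects was tested as an interaction, and 2 of 11287 genes passed in edgeR, with 564 at an unadjusted p under 0.05. DESeq2 called 17 and limma on FPKM values 23. Ctss, which encodes cathepsin S, was at 139 CPM with TGFb and 213 with vitamin C, but at 67.4 and 45 CPM with retinoic acid present (difference -1.20 ± 0.14, edgeR, adjusted p = 0.00314). Itgb1, the beta-1 integrin chain, was at 393 and 778 CPM without and at 320 and 320 CPM with retinoic acid (difference -0.99 ± 0.13, adjusted p = 0.00649). Its call was lost without retinoic acid plus vitamin C 2 (0.0569), without TGFb 1 (0.0727) and without vitamin C 1 (0.0638). None of the 17 tested followed genes passed, namely Foxp3 (-0.36 ± 0.13), Tet1 (0.03 ± 0.36), Tet2 (-0.40 ± 0.23), Tet3 (-0.21 ± 0.21), Dnmt1 (0.13 ± 0.16), Dnmt3a (0.00 ± 0.14), Dnmt3b (0.27 ± 0.21), Il2ra (-0.08 ± 0.12), Ctla4 (-0.05 ± 0.21), Ikzf2 (-0.41 ± 0.19), Ikzf4 (-0.31 ± 0.26), Tnfrsf18 (-0.32 ± 0.21), Nrp1 (-0.87 ± 0.19), Itgae (0.97 ± 0.50), Gata3 (-0.48 ± 0.13), Bcl6 (-0.64 ± 0.24) and Ccr9 (0.18 ± 0.90). Of these Nrp1 passed in DESeq2 (0.0278), with no count filter (0.0463) and without retinoic acid 2 (0.0483). Of 29 lists 13 passed camera and 0 with an estimated correlation or by fry.

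TGFb iTreg cells were compared with Th0 cells to show what TGFb added to activation (n = 2 and 2 libraries). Foxp3 rose 33.7-fold, from 16.2 ± 0.48 to 549 ± 13 CPM (5.08 ± 0.12, edgeR quasi-likelihood test, adjusted p = 4.79e-13). Ikzf2 rose 12.3-fold (3.62 ± 0.18) and Gpr83, an orphan receptor of Treg cells, 11.9-fold (3.58 ± 0.32). The inhibitory receptor gene Ctla4 (1.87 ± 0.16), the IL-2 receptor alpha chain, Il2ra (1.11 ± 0.09), Nrp1 (2.38 ± 0.16) and the GITR gene Tnfrsf18 (0.85 ± 0.15) rose too. Of the Treg core list 26 of 30 rose and 4 did not pass (28 adjusted over the list alone, camera adjusted p = 2.12e-50, or adjusted p = 0.0113 with an estimated correlation). In the TGF-beta list 12 of 22 rose, 1 fell and 9 did not pass (14 and 1 adjusted over the list alone, camera adjusted p = 1.97e-06, or adjusted p = 0.0572 with an estimated correlation), with Skil (2.13 ± 0.13) and the pseudoreceptor gene Bambi (1.71 ± 0.31). In the IL-2 and STAT5 list 14 of 24 rose, 3 fell and 7 did not pass (17 and 3 adjusted over the list alone, camera adjusted p = 8.41e-05, or adjusted p = 0.0572 with an estimated correlation), with Il2rb (1.21 ± 0.10) up and the kinase gene Pim2 (-2.49 ± 0.16) down. In the Th17 list 5 of 7 rose and 2 did not pass (5 adjusted over the list alone, camera adjusted p = 1.51e-05, or adjusted p = 0.0572 with an estimated correlation), with Tmem176a (2.41 ± 0.19) and Tmem176b (2.22 ± 0.19). In the Th1 list 8 of 16 rose, 1 fell and 7 did not pass (8 and 1 adjusted over the list alone, camera adjusted p = 0.00194, or adjusted p = 0.112 with an estimated correlation), with Il12rb2 (2.80 ± 0.34) and Nkg7 (2.49 ± 0.37). In the early T cell receptor list 13 of 26 rose and 13 did not pass (13 adjusted over the list alone, camera adjusted p = 0.000117, or adjusted p = 0.338 with an estimated correlation). The orphan nuclear receptor genes Nr4a1 (1.64 ± 0.23) and Nr4a3 (2.21 ± 0.43) and Egr1 (1.62 ± 0.35) rose.

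Division and biosynthesis genes fell. In the cell cycle list 21 of 40 fell and 19 did not pass (22 adjusted over the list alone, camera adjusted p = 2.28e-06, or adjusted p = 0.338 with an estimated correlation), with Mcm3 (-0.52 ± 0.09) and Tyms (-0.53 ± 0.11). In the amino acid stress list 12 of 21 fell, 1 rose and 8 did not pass (14 and 2 adjusted over the list alone, camera adjusted p = 0.000144, or adjusted p = 0.338 with an estimated correlation), with the stress factor gene Atf4 (-0.78 ± 0.13). In the cholesterol list 16 of 29 fell, 2 rose and 11 did not pass (18 and 2 adjusted over the list alone, camera adjusted p = 0.000131, not passing with an estimated correlation). Large rises were those of Hbb-b1 (6.17 ± 0.51) and Hbb-bs (5.65 ± 0.34), beta-globin genes, Ifitm1 (5.39 ± 0.23), the tyrosine kinase gene Fes (4.94 ± 0.29) and Car5b (4.90 ± 0.20). Kit rose 9.29-fold (3.22 ± 0.22). Large falls were those of Ctnnd2 (-6.30 ± 0.31), the homing receptor gene Cxcr6, 34.5-fold (-5.11 ± 0.42), and Pou2af1 (-4.04 ± 0.32).

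Of the followed genes 9 rose, 2 fell and 6 did not pass. Also rising were Ikzf4 (1.12 ± 0.21), Bcl6 (1.17 ± 0.22) and Itgae (2.07 ± 0.59), the last a call lost in limma on FPKM values (0.0897), without TGFb 2 (0.15), without Th0 1 (0.106) and without Th0 2 (0.0871) (adjusted p, by edgeR unless named). Tet1 (-1.50 ± 0.24) fell, and so did Dnmt3a (-0.39 ± 0.10), a call lost without TGFb 2 (0.12) and without Th0 1 (0.0646). Not passing were Tet2 (-0.27 ± 0.16), Tet3 (-0.13 ± 0.15), Dnmt1 (-0.27 ± 0.11), Dnmt3b (0.35 ± 0.16), Gata3 (-0.01 ± 0.09) and Ccr9 (-0.57 ± 0.74). Of these Dnmt1 passed with only the compared groups fitted (0.0141). In edgeR 2943 of 11287 genes changed, 1631 higher and 1312 lower. The count was 1539 and 1772 without TGFb 1 and 2, and 1480 and 1945 without Th0 1 and 2. Of 29 lists 18 passed camera, 1 with an estimated correlation, and 19 passed fry.

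Activation of naive CD4+ cells through CD3 and CD28 without TGFb (Th0, n = 2) was compared with naive cells (n = 2). Il2ra rose from 2.87 ± 0.25 to 1430 ± 190 CPM (8.95 ± 0.14, edgeR quasi-likelihood test, adjusted p = 1.28e-15). In the cell cycle list 40 of 40 rose (40 adjusted over the list alone, camera adjusted p = 3.04e-81, or adjusted p = 0.0139 with an estimated correlation), with the mitotic kinase gene Aurkb 214-fold (7.74 ± 0.21) and cyclin A2, Ccna2 (7.52 ± 0.18), up. In the glycolysis list 19 of 23 rose, 3 fell and 1 did not pass (19 and 3 adjusted over the list alone, camera adjusted p = 4.47e-07, or adjusted p = 0.353 with an estimated correlation), with Hk2 322-fold up (8.33 ± 0.39). In the cholesterol list 27 of 29 rose and 2 fell (27 and 2 adjusted over the list alone, camera adjusted p = 3.12e-14, or adjusted p = 0.265 with an estimated correlation), with Idi1 (3.29 ± 0.13) and Tmem97 (3.88 ± 0.16). In the IL-2 and STAT5 list 16 of 24 rose, 7 fell and 1 did not pass (16 and 7 adjusted over the list alone, camera adjusted p = 4.47e-07, or adjusted p = 0.0636 with an estimated correlation), with the signalling suppressor gene Socs2 (10.39 ± 0.17) up. Naive and memory genes fell, and so did genes of the interferon and early T cell receptor responses. In the naive and memory list 21 of 24 fell, 2 rose and 1 did not pass (21 and 2 adjusted over the list alone, camera adjusted p = 2.19e-11, or adjusted p = 0.0636 with an estimated correlation), with the IL-7 receptor gene Il7r 25.9-fold lower (-4.69 ± 0.20) and Sidt1 (-3.41 ± 0.13). In the interferon list 37 of 45 fell, 2 rose and 6 did not pass (37 and 2 adjusted over the list alone, camera adjusted p = 6.26e-09, or adjusted p = 0.356 with an estimated correlation), with Ifit3 (-5.54 ± 0.39) and Ifi44 (-5.40 ± 0.45). In the early T cell receptor list 20 of 26 fell, 3 rose and 3 did not pass (20 and 3 adjusted over the list alone, camera adjusted p = 8.63e-10, or adjusted p = 0.187 with an estimated correlation), with Egr1 (-6.53 ± 0.25) and Egr2 (-6.01 ± 0.33) down. Fads2, a fatty acid desaturase gene, was at 0 in naive cells and rose at least 820-fold. Dtx1, a Notch regulator, had 1 count in Th0 cells and 8058 in naive cells (8370-fold, exact 95% counting interval 1500 to 330000).

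Of the followed genes 7 rose, 5 fell and 5 did not pass. Also rising were Ctla4 (4.18 ± 0.22), Tnfrsf18 (1.97 ± 0.16), Nrp1 (1.21 ± 0.20), Gata3 (0.42 ± 0.09), Dnmt1 (2.07 ± 0.12) and Ikzf4 (0.66 ± 0.25), the last a call lost with only the compared groups fitted (0.0636), without naive 1 (0.298) and without Th0 2 (0.26) (adjusted p by edgeR). The falls were those of Foxp3 (-0.74 ± 0.12), Ccr9 (-5.12 ± 0.31), Tet1 (-2.20 ± 0.18), Tet3 (-1.40 ± 0.15) and Bcl6 (-3.65 ± 0.18). Not passing were Tet2 (0.16 ± 0.17), Dnmt3a (0.20 ± 0.10), Dnmt3b (-0.15 ± 0.16), Ikzf2 (0.18 ± 0.26) and Itgae (0.32 ± 0.87). Of these Dnmt3a passed with only the compared groups fitted (0.0272). In edgeR 8131 of 11287 genes changed, 4025 higher and 4106 lower. Of 29 lists 12 passed camera, 1 with an estimated correlation, and 26 passed fry.

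Control Treg cells sorted ex vivo (n = 4) were compared with naive CD4+ cells (n = 2) for a signature of Treg cells. The mice differed in age and genotype. The Y-linked gene Ddx3y was counted in every Treg library and at 0 in both naive libraries (at least 576-fold higher), so cell type, age, genotype and sex cannot be told apart here. Foxp3 was 23.2-fold higher in Treg cells (4.53 ± 0.11, edgeR quasi-likelihood test, adjusted p = 7.5e-10), Il2ra 339-fold (8.41 ± 0.13), Ctla4 64.8-fold (6.02 ± 0.22) and Ikzf2 90.6-fold (6.50 ± 0.19). Fgl2, a secreted immunoregulatory protein gene, was at least 684-fold higher, and Klrg1 had 4932 counts against 1 (1540-fold, exact 95% counting interval 277 to 60900). In the Treg core list 33 of 34 rose and 1 did not pass (33 adjusted over the list alone, camera adjusted p = 7.95e-121, or adjusted p = 0.00393 with an estimated correlation). In the effector Treg list 20 of 20 rose (20 adjusted over the list alone, camera adjusted p = 8.22e-43, or adjusted p = 0.0216 with an estimated correlation), with Il1rl1 at least 424-fold higher. In the homing list 16 of 25 rose, 4 fell and 5 did not pass (16 and 6 adjusted over the list alone, camera adjusted p = 1.52e-16, or adjusted p = 0.0427 with an estimated correlation), with Ccr6 at least 376-fold and Cxcr3 (7.16 ± 0.34). In the naive and memory list 21 of 24 fell, 1 rose and 2 did not pass (21 and 1 adjusted over the list alone, camera adjusted p = 6.81e-20, or adjusted p = 0.0298 with an estimated correlation), with Pdlim4 (-6.44 ± 0.19), Als2cl (-4.15 ± 0.17) and Dapl1 (-3.57 ± 0.11) down. In the early T cell receptor list 16 of 26 fell, 6 rose and 4 did not pass (16 and 6 adjusted over the list alone, camera adjusted p = 3.63e-06, or adjusted p = 0.138 with an estimated correlation), with Jun (-5.02 ± 0.19) and Fos (-4.63 ± 0.24) down. Markers of other cells were higher too. Of B cell markers 16 of 19 rose and 3 did not pass (18 adjusted over the list alone, camera adjusted p = 0.000312, or adjusted p = 0.493 with an estimated correlation), summing to 277 ± 110 against 12.3 ± 3.7 CPM. Of erythroid and platelet markers 6 of 8 rose and 2 did not pass (7 adjusted over the list alone, camera adjusted p = 0.000249, or adjusted p = 0.231 with an estimated correlation), summing to 669 ± 240 against 9.73 ± 1.8 CPM. Mia3 (at least 3680-fold lower), Ccdc82 (at least 2320-fold) and Hmgcs1 (at least 1320-fold) were at 0 in every Treg library, a pattern weighed in the closing section.

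Of the followed genes 14 were higher, 3 lower and 3 did not pass, and Il4, Il13, Il17a and Il2 were under the count filter. Also higher were Ikzf4 (3.47 ± 0.20), Nrp1 (5.75 ± 0.15), Tnfrsf18 (2.42 ± 0.10), Itgae (9.48 ± 0.24), Tbx21 (4.58 ± 0.37), Gata3 (0.53 ± 0.10), Dnmt3a (0.41 ± 0.09) and Il10 (at least 34.7-fold). Ifng was higher too (11.1-fold, exact 95% counting interval 2.96 to 93.4), its log2 fold change moving without naive 2 (7.03). The rise of Ccr9 (0.82 ± 0.24) was lost without naive 1 (0.137) and without naive 2 (0.0643) (adjusted p, by edgeR unless named). Lower were Tet1 (-1.31 ± 0.22), Tet3 (-0.94 ± 0.12) and Tet2 (-0.48 ± 0.18), the last a call lost in DESeq2 (0.0667), with RLE factors (0.0519), in limma on FPKM values (0.184), without naive 1 (0.202), without naive 2 (0.131), without control S2 (0.0658) and without control S3 (0.0717). Not passing were Dnmt1 (-0.07 ± 0.11), Dnmt3b (-0.28 ± 0.16) and Bcl6 (0.18 ± 0.28), of which Bcl6 passed without control S1 (0.0463). In edgeR 6439 of 11738 genes changed, 3357 higher and 3082 lower (52.1% higher). With limma on the FPKM values the split was 4205 and 2202 (65.6% higher), with a median of all genes of 0.12 against 0.01. Of 30 lists 22 passed camera, 9 with an estimated correlation, and 26 passed fry.

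Cells that were Foxp3-negative after restimulation were compared with Foxp3-positive iTreg sorted at day 6 (n = 3 and 3 libraries). The groups differed in time, restimulation and Foxp3 status together, so these cannot be separated. Foxp3 fell 22.2-fold, from 334 ± 18 to 14.9 ± 2.2 CPM (-4.47 ± 0.09, edgeR quasi-likelihood test, adjusted p = 6.52e-15). Other Treg genes fell too, Il2ra 4.67-fold (-2.22 ± 0.06), Ctla4 3.68-fold (-1.88 ± 0.06), Ikzf2 4.79-fold (-2.26 ± 0.14) and Gpr83 93.6-fold (-6.55 ± 0.28). Tnfrsf9, which encodes 4-1BB, fell 65.8-fold (-6.04 ± 0.25). Of the Treg core list 24 of 31 fell, 6 rose and 1 did not pass (24 and 6 adjusted over the list alone, camera adjusted p = 1.18e-12, or adjusted p = 0.127 with an estimated correlation), with Itgae among the rises, 15.6-fold (3.97 ± 0.27).

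Th1, homing and killer genes rose. The chemokine receptor genes Cxcr3, Cxcr6 and Ccr2 rose 240-fold (7.91 ± 0.13), 145-fold (7.18 ± 0.14) and 89.7-fold (6.49 ± 0.09), and the Th1 factor gene Tbx21 65.1-fold (6.02 ± 0.22). In the Th1 list 15 of 17 rose, 1 fell and 1 did not pass (15 and 1 adjusted over the list alone, camera adjusted p = 7.94e-19, or adjusted p = 0.0222 with an estimated correlation), with Eomes (3.97 ± 0.17). In the homing list 19 of 23 rose, 2 fell and 2 did not pass (19 and 2 adjusted over the list alone, camera adjusted p = 1.1e-13, or adjusted p = 0.0222 with an estimated correlation). In the cytotoxic list 9 of 13 rose, 3 fell and 1 did not pass (9 and 4 adjusted over the list alone, camera adjusted p = 3.08e-06, or adjusted p = 0.0621 with an estimated correlation), with Nkg7 30.1-fold up (4.91 ± 0.11), Klrd1 (5.53 ± 0.24), an NK receptor chain, and Ctsw (2.78 ± 0.07). Of invariant NKT markers 6 of 7 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 1.2e-15, or adjusted p = 0.02 with an estimated correlation), summing to 1010 ± 14 against 841 ± 75 CPM. In the naive and memory list 19 of 24 rose, 4 fell and 1 did not pass (19 and 4 adjusted over the list alone, camera adjusted p = 0.000243, or adjusted p = 0.326 with an estimated correlation). The resting T cell factor gene Tcf7 (2.12 ± 0.07) and S1pr1 (2.08 ± 0.06) rose.

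Metabolic genes fell. In the glycolysis list 21 of 22 fell and 1 did not pass (21 adjusted over the list alone, camera adjusted p = 2.4e-67, or adjusted p = 0.02 with an estimated correlation), with Slc16a3 37.9-fold lower (-5.25 ± 0.09), Aldoc (-4.61 ± 0.07) and Tpi1 (-3.69 ± 0.07). In the hypoxia list 23 of 25 fell and 2 did not pass (23 and 1 adjusted over the list alone, camera adjusted p = 1.19e-48, or adjusted p = 0.0222 with an estimated correlation). The angiogenic factor gene Vegfa fell 147-fold (-7.20 ± 0.23) and Ak4 545-fold (-9.09 ± 0.16). In the cholesterol list 27 of 28 fell and 1 did not pass (27 adjusted over the list alone, camera adjusted p = 5.93e-19, or adjusted p = 0.16 with an estimated correlation), with Scd1 (-5.53 ± 0.25) and Fdps (-2.86 ± 0.14). The glucose transporter genes Slc2a1 (-2.27 ± 0.06) and Slc2a3 (-2.80 ± 0.07) fell. In the cell cycle list 29 of 40 fell and 11 did not pass (32 adjusted over the list alone, camera adjusted p = 0.000191, or adjusted p = 0.476 with an estimated correlation), with Mki67 (-1.32 ± 0.07) down. In the early T cell receptor list 16 of 26 fell, 6 rose and 4 did not pass (17 and 6 adjusted over the list alone, camera adjusted p = 0.00815, or adjusted p = 0.326 with an estimated correlation), with Nr4a1 78.2-fold lower (-6.29 ± 0.22) and Egr3 (-4.49 ± 0.23). Hbb-b1 and Hbb-bs, at 47.6 ± 16 and 22.1 ± 7.2 CPM at day 6, were at 0 after restimulation (at least 660-fold and at least 307-fold lower). The antigen presentation genes Cd74 (-6.17 ± 0.40) and H2-Ab1 (-5.78 ± 0.18) fell, and B cell markers summed to 5.1 ± 0.51 against 119 ± 19 CPM. Large rises were those of Ctnnd2 (7.47 ± 0.14), Nebl (7.20 ± 0.24) and the T cell surface protein gene Cd7 (5.91 ± 0.17) and falls of Tgm2 (-7.55 ± 0.21), a transglutaminase gene, and Mgarp (-8.08 ± 0.19).

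Of the followed genes 6 rose, 10 fell and 1 did not pass, Dnmt3b (-0.09 ± 0.11). Also rising were Tet1 (1.04 ± 0.18), Tet3 (1.40 ± 0.08), Dnmt3a (0.24 ± 0.07) and Gata3 (0.72 ± 0.06). Also falling were Tnfrsf18 (-1.89 ± 0.09), Nrp1 (-2.26 ± 0.08), Ikzf4 (-0.54 ± 0.11), Bcl6 (-1.27 ± 0.15), Dnmt1 (-0.35 ± 0.07) and Tet2 (-0.67 ± 0.23), the last a call lost with no count filter (0.0933), without day 6 2 (0.0872), without restimulated 1 (0.0796) and without restimulated 2 (0.0529) (adjusted p by edgeR). Ifng, Il4, Il13, Il17a, Ccr9, Il2 and Il10 were under the count filter. In edgeR 7745 of 11252 genes changed, 3783 higher and 3962 lower, or 4288 and 3437 in limma on FPKM values. Of 25 lists 16 passed camera, 6 with an estimated correlation, and 25 passed fry.

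**Figure D2:**
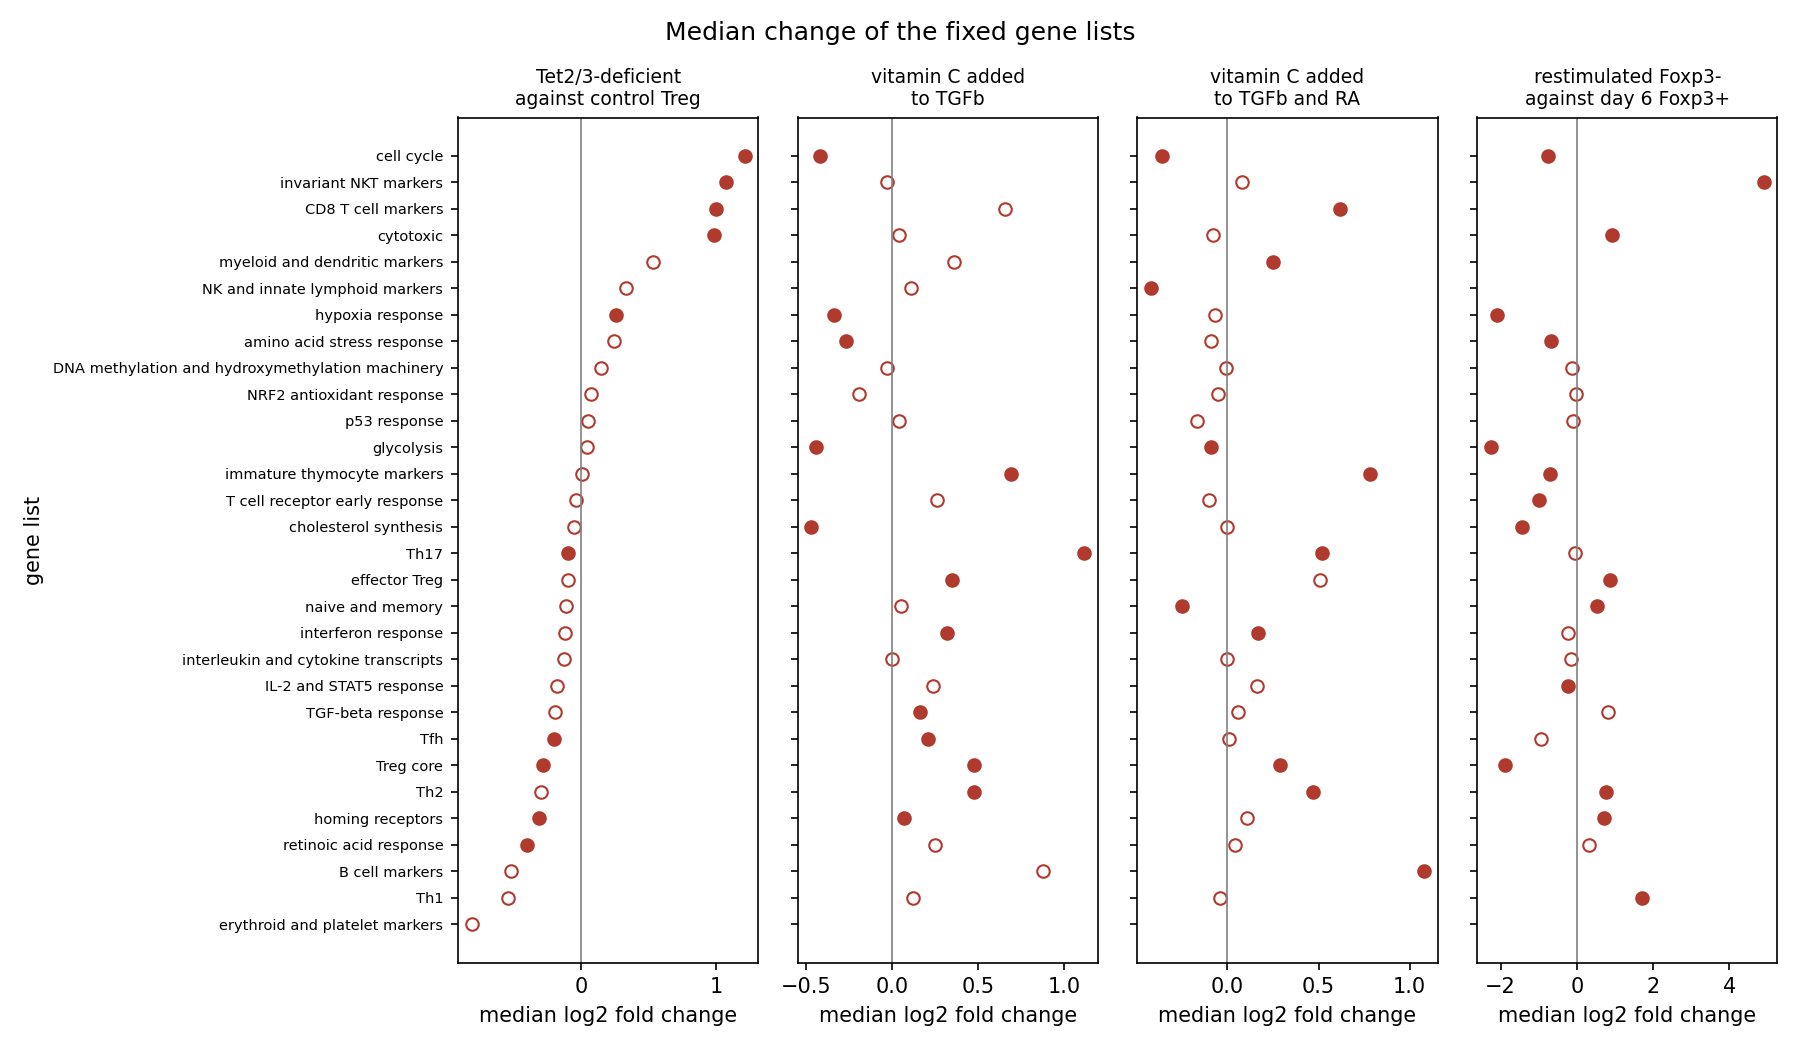
Median log2 fold change of the genes of each fixed list in 4 comparisons, each on its own scale, with filled points where camera gave an adjusted p under 0.05 and open points where it did not. The cell cycle list was at 1.21 in Tet2/3-deficient Treg cells and at -0.42 with vitamin C.

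**Figure D3:**
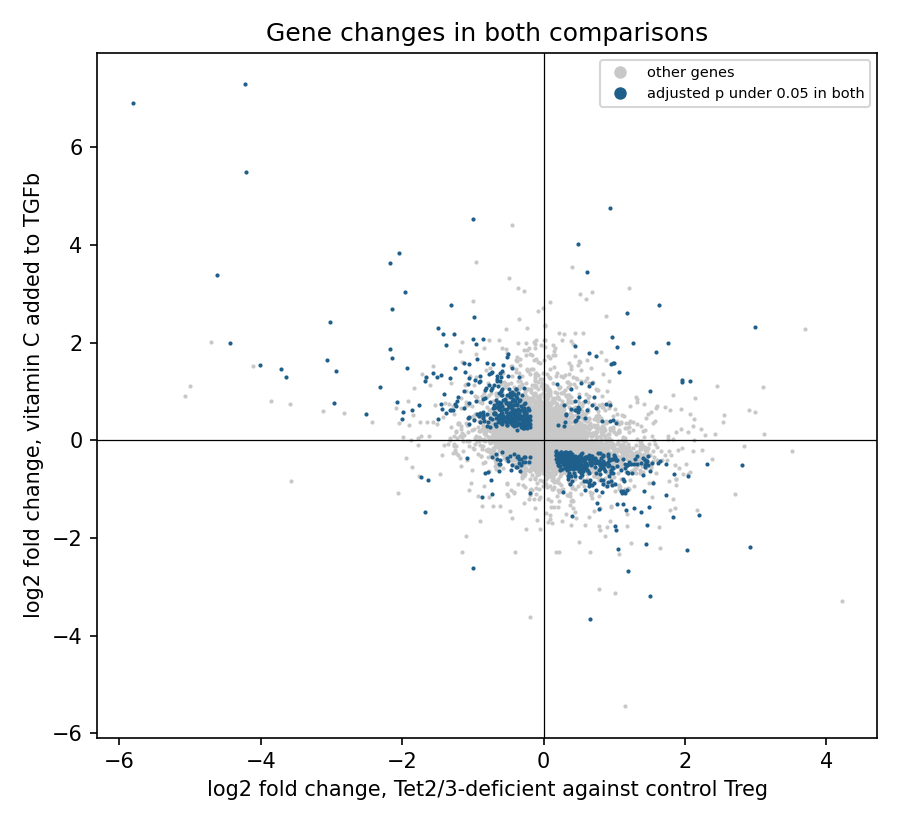
Fitted log2 fold change of each gene tested in both comparisons, Tet2/3-deficient against control Treg on the horizontal and vitamin C added to TGFb on the vertical axis. Dark points passed in both, and 448 of them lie at lower right and 368 at upper left.

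Of the genes that changed in Tet2/3-deficient Treg cells, more moved the opposite way than the same way with vitamin C, and most did not pass there. Of 1792 tested genes higher in Tet2/3-deficient cells 448 fell with vitamin C, where 144.7 would by independent calls, and 56 rose, where 156.1 would. Their median log2 fold change with vitamin C was -0.234 (camera adjusted p = 3.72e-15, or adjusted p = 0.0314 with an estimated correlation). Of 1768 genes lower in Tet2/3-deficient cells 368 rose with vitamin C against 154 and 40 fell against 142.8, with a median of 0.172 (camera adjusted p = 2.93e-12, or adjusted p = 0.0432 with an estimated correlation). Plagl1, Ccr6 and Pdcd1 were among the 368. The 448 included Tmem97 (0.95 ± 0.15 and -0.85 ± 0.13) and replication genes Pcna, Cdc45 and Mcm2 to Mcm7. Cell cycle list medians were 1.21 and -0.42. With the expected numbers summed over 20 classes of the Th0 against naive fold change, they were 286.6 and 213.9, so 448 and 368 were 1.56 and 1.72 times them. Across 10920 genes, which are not independent replicates, both log2 fold changes had a Pearson correlation of -0.36 and a Spearman one of -0.42.

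With retinoic acid present, genes higher in Tet2/3-deficient cells were again lower with vitamin C, with a median of -0.165 (camera adjusted p = 3.87e-10, or adjusted p = 0.0432 with an estimated correlation) and 153 lower against 57.9. Genes lower in Tet2/3-deficient cells were higher, with a median of 0.092 (camera adjusted p = 4.89e-07, or adjusted p = 0.113 with an estimated correlation) and 168 higher against 73. Without retinoic acid 2 these medians were -0.105 and 0.057, and without retinoic acid 1 -0.209 and 0.142. In the restimulation comparison the first set had a median of -0.255 (camera adjusted p = 0.00052, or adjusted p = 0.311 with an estimated correlation) and the second 0.22 (camera adjusted p = 0.000993, or adjusted p = 0.227 with an estimated correlation). When set members needed a log2 fold change of 1 or more, these medians were -0.492 (adjusted p = 0.188) and -0.29 (adjusted p = 0.323), so the second turned direction.

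Genes of the control Treg signature did not pass camera as sets in either vitamin C comparison, though more of the higher genes rose than independent calls would give. With vitamin C 428 of these rose against 242.8 expected and 246 fell against 223.7, and with retinoic acid present 258 rose against 115.7 and 114 fell against 88.9. The 2798 genes higher in control Treg than naive cells had a median of 0.035 with vitamin C (camera adjusted p = 0.0641), which passed at 0.176 when members needed a log2 fold change of 1 or more (adjusted p = 1.62e-05), and of -0.001 with retinoic acid (adjusted p = 0.117, or 0.00366 at 0.047). The first also passed without TGFb 1 (0.056, adjusted p = 0.0331) and without vitamin C 2 (0.045, adjusted p = 0.0113), and the second without retinoic acid 2 (0.035, adjusted p = 0.0157). The 3056 lower genes had medians of 0.032 (adjusted p = 0.524) and 0 (adjusted p = 0.622), the latter at -0.037 without retinoic acid 2 (adjusted p = 0.0118). Of them 237 rose with vitamin C against 265.2 and 184 fell against 244.3, and 79 and 109 did with retinoic acid present against 126.3 and 97.1. In restimulated cells the higher set fell, with a median of -0.212 (camera adjusted p = 0.000653, or adjusted p = 0.114 with an estimated correlation), and the lower set rose, with a median of 0.194 (camera adjusted p = 2.52e-06, or adjusted p = 0.131 with an estimated correlation).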

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

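The tests of the genes at 0, of the beta-globin transcripts and within classes of the Th0 against naive fold change were chosen only after the result was seen. Among 175 sets of 4 libraries tested for a sample far from the others 11 stood out, and chance gives about 1 in 20. In control Treg cells these were the highest libraries for Eomes (S4, 5.34 CPM, next 3.71), Prg4 (S4, 57.4, next 38.3), Rarg (S4, 124, next 112), Mbd4 (S3, 12, next 10.5), Nrn1 (S3, 71.6, next 59.7) and Trib3 (S1, 14.3, next 6.9). The summed invariant NKT markers stood out in control S1 (1760 CPM, next 1550). In Tet2/3-deficient cells Cd8a (S5, 1.94 CPM, next 1.13), Mbd4 (S8, 18.7, next 16) and Tnfrsf18 (S7, 307, next 285) had a high library and Cish a low one (S5, 94.9, next 111). The vitamin C effect differed with retinoic acid for Ctss (log2 -1.2) and Itgb1 (-0.99).

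Genes higher in Tet2/3-deficient Treg cells fell with vitamin C and the reverse, more often than independent calls give. Within 10 classes of gene length the lower of both ratios of seen to expected genes was 2.06, and within 10 classes of mean expression 2.33, which argues against length or expression level as the whole cause. Among 3011 genes not called between Th0 and naive cells the lower ratio was 2.24, from 20 genes against 8.928, with an exact lower limit of 1.37. The need for this limit to reach 1.5 was set after that ratio was seen, which by itself had met the bound, and turned the verdict from against activation to open. Within 20 classes of the Th0 against naive fold change the lower ratio was 1.56, with a limit of 1.42, so a difference in activation stays open.

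A set of 15 genes was listed at 0 in all 14 ex vivo Treg and restimulation libraries and had at least 10 counts in each of the 12 others. Of these 11 had another member within 10 annotated genes, where the largest of 10000 random lists had 6, as counting or mapping that differed between sets of libraries would give. Their median log2 fold change of 0.01 in TGFb iTreg against Th0 cells decides nothing, since they were chosen for counts in both. From TGFb iTreg to day 6 iTreg, 15 genes went from 50 or more counts per library to 0. All were 0 in the 11 ex vivo Treg and Foxp3-negative (once iTreg) libraries, so silencing in Treg cells is open. Comparisons across these sets of libraries may carry such differences, and without these and sex-linked genes 6419 genes changed between control Treg and naive cells.

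Beta-globin transcripts were at 48.2 to 59.5 CPM in TGFb iTreg, 0.683 to 0.893 CPM in Th0 and 0.504 to 0.726 CPM in naive libraries. Carry-over of erythroid cells would need 218 counts of Slc4a1 and Alas2 in the 5 TGFb iTreg libraries, from their ratio in ex vivo Treg libraries, and 14 were seen, with an upper limit of 23.5. The lowest TGFb iTreg library exceeded the highest Th0 library 54 times, which restates that both copies rose, and reads moved between the copies leave their sum as it was. Expression in the cultured cells may remain as a hypothesis, and carry-over of RNA without cells was not tested.

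Of 35 splits of the 8 Treg libraries into 4 and 4, only the real one called genes (3800). Splits that mix the groups cannot exclude a chance difference between mice. For lists 7 splits called 10 or more, with 14 the highest other, so chance is not excluded for the number of lists. The 10 splits of the restimulation libraries are too few for a share under 0.05, and 1 split, the real one, was as large in each case. The real values and highest others were 7745 and 0 genes, 16 and 13 lists, and medians of -0.255 and 0.129, 0.22 and 0.101, -0.212 and 0.101, and 0.194 and 0.0911.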

How the results depend on the processing

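Analyses without control S1 and S3 and without sex-linked genes and genes at 0 in 1 set of libraries were chosen only after the result was seen. Of 4593 values of named genes under alternatives 4385 kept their direction and side of the threshold, 167 lost the call, 41 gained one and 0 reversed. Counts of changed genes stayed within 1.5 times with DESeq2, RLE factors, no filter and limma on FPKM, except for the interaction, whose 2 genes became 17 with DESeq2, 25 with no filter and 23 with limma. Requiring a log2 fold change of 1 left 642 genes in Tet2/3-deficient cells, 339 with vitamin C, 476 with retinoic acid, 286 with vitamin C beside retinoic acid, 1 for the interaction, 654 for TGFb, 3629 for Th0, 2608 for control Treg and 1727 for restimulation, by its own construction. With only the compared groups fitted, vitamin C beside retinoic acid gave 487. A replicate block gave 1363 there and 26 for the interaction, and 2827, 2583, 3864, 8429 and 8003 for vitamin C, retinoic acid, TGFb, Th0 and restimulation. Of named calls the block lost 0 and gained 14. Of these vitamin C gained Tet2, Tet3, Dnmt1 and Ctla4, and retinoic acid Tet3, Dnmt3a, Tnfrsf18 and Ctla4. Vitamin C beside retinoic acid gained Ctla4, Ikzf4 and Il2ra, and the interaction Nrp1. Replicate numbers of the cultured groups are not stated to pair samples. They correlated at 0.22 to 0.42 among the 4 iTreg cultures and 0.01 to 0.09 with Th0 or naive cells. In restimulation each number correlated best with its own, at 0.08, 0.1 and 0.2. The Tet2/3-deficient and control Treg columns carry no replicate numbers to pair.

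Leaving out 1 library gave 2831 to 4141 genes for Tet2/3-deficient cells, 771 to 1001 for vitamin C, 795 to 1898 for retinoic acid, 424 to 899 for vitamin C beside retinoic acid, 1 to 11 for the interaction, 1480 to 1945 for TGFb, 7331 to 7407 for Th0, 4402 to 6755 for control Treg and 7120 to 7713 for restimulation. A group left with 1 library was assumed to vary like the others. Calls became fewer in most of these runs, and the cause was not tested. Without control S1 and S3, 4277 genes changed in Tet2/3-deficient cells. Of 259 list tests camera called 132, 18 with an estimated correlation, and fry 154. The estimated correlation ended the calls of the sets with medians of 0.092 beside retinoic acid and of -0.255, 0.22, -0.212 and 0.194 in restimulation. Set members with a log2 fold change of 1 or more gave medians of 0.176 and 0.047 for genes higher in control Treg cells in both vitamin C comparisons, which then passed. In restimulation they gave -0.492 and, reversed, -0.29 for genes higher and lower in Tet2/3-deficient cells, and the cause was not tested. For genes higher in control Treg cells, leaving out 1 library gave medians of 0.009 to 0.056 with vitamin C and -0.017 to 0.035 beside retinoic acid, and for lower genes there -0.037 to 0.058. In simulation edgeR recovered 50.7% of 1.5-fold changes at the size of the Tet2/3-deficient comparison, so smaller changes can be missed.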

Other observations

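These globin ranges were picked only after they were seen. Summed beta-globin was at 23.4 to 31.7 CPM with vitamin C, 0.85 to 3.61 with retinoic acid, 1.06 to 1.12 with both and 0 after restimulation. The alpha-globin gene Hba-a2 was at 31.1 to 42.4, 38 to 67.8, 7.41 to 14.1 and 21.4 to 27 CPM there, and at 93.8 to 134 CPM in TGFb iTreg and 96.1 to 134 CPM in Th0 libraries. In edgeR tests Hba-a2 fell with vitamin C (-1.66 ± 0.36, adjusted p = 0.0191), a call lost without TGFb 1 (0.119), without vitamin C 1 (0.0753) and without vitamin C 2 (0.137). With vitamin C beside retinoic acid it fell (-2.30 ± 0.42, adjusted p = 0.015), a call lost without retinoic acid 2 (0.109), without retinoic acid plus vitamin C 1 (0.132) and without retinoic acid plus vitamin C 2 (0.0664).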
